A study of Arabidopsis thaliana with 6 samples.

How the data were processed

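Gene expression was measured in inflorescences of Arabidopsis thaliana, accession Landsberg erecta, carrying 35S::SUP-GR. This transgene places SUPERMAN (SUP), a zinc-finger protein of the flower, fused to the hormone-binding part of the glucocorticoid receptor, under a strong viral promoter. Such fusions are generally held out of the nucleus until dexamethasone (DEX) is given. Per the labels, plants grew at 22 °C in continuous light, inflorescences were submerged for 1 min in DEX or in the same amount of ethanol (Mock), with 0.015% Silwet L-77, and buds younger than flower stage 10 were taken 4 hours later. The dose was 10 µM, diluted from a 30 mM stock; the labels write the dose unit as a length, and it was read as a concentration. The labels also state total RNA with on-column DNase digestion and a Cy3 label on NimbleGen arrays.

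The authors deposited RMA values as linear intensity, per the submitters' processing notes and the range of the values, from 0.482 to 3642.22. The version of RMA, the background step and the probe design are not given in the sources used here. The deposited intensity table has 39640 rows, each a locus with a feature number. Of these, 2522 rows hold no value on any array, which left 37118. Quartiles were nearly equal between arrays, so the values were kept as normalized by the authors. The log2 of each intensity was taken with no pseudocount. Where a locus had several features, as 3602 had, the feature with the highest mean over all arrays stood for the gene, which gave 32627 genes and left 4491 further features aside. No filter on dim genes was applied. Of the 32627 loci, 31993 matched the RefSeq gene table of assembly TAIR10.1, which was used for symbols and locus classes only. Organelle loci were recognised by their locus names.

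DEX was compared with Mock, 3 arrays in each group, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, two-sided). The p-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05 and no fold minimum. The stated design expected log2 values, and the unit proved linear, so log2 was taken first, as that design provided. Changes are log2 differences, DEX minus Mock, with the standard error (SE) from the fit, and group values are mean ± SD of log2 intensity. An exact two-sided permutation test over the 20 relabelings of the arrays was added for SUP, YUC1 and YUC4; its smallest possible p is 0.1. For 23 gene lists holding 374 genes, all measured, limma's camera was run with a preset correlation between genes of 0.01, adjusted over the lists. Lists, tests, most other settings and the naming rule were fixed before the data were examined.

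The rule named SUP, YUC1, YUC4, AP3, PI, AG, WUS, CUC1 and CUC2 always. It added the 12 largest rises and 12 largest falls past the threshold with no overlap between groups. A direction with fewer than 12 was filled by the smallest unadjusted p, and such genes are said not to have passed. Up to 4 members of each list with the smallest unadjusted p serve as examples.

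The other settings tried were a replicate block (fixed and random), 2 filters on dim genes, quantile normalization and median centring, a trended and robust prior, array weights, other uses of features, other call rules, and leaving out each array. For lists they included an estimated correlation and fry. Added after the data were seen were 16 added to each intensity, the block with the trended and robust prior, and that prior with Mock replicate 1 left out.

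The fits were tested on simulated data for DEX against Mock, with the real means of 32627 genes. Spreads were drawn around a smooth curve of the real spread on mean intensity. The simulated spread thus follows intensity by construction, which favours the trended and robust prior. Its lead there does not show that it suits the real arrays better. Of 100 changed genes brighter than the median, each changed by 2 on the log2 scale, the default prior recovered 89 and the trended and robust prior 97. For 100 genes changed by 1, they recovered 31 and 80. The numbers of false calls were 4 and 5. Arrays give no read depth, and the number of arrays limits the precision. The sources mention independent sets, but nothing says that replicates came from separate plantings, so p-values measure only the spread between these samples.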

Results

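Transcript levels were measured on 6 arrays, 3 of ethanol-treated (Mock) and 3 of DEX-treated 35S::SUP-GR inflorescences, 4 hours after treatment. Each array gave values for 37118 features. Median intensities ranged from 74.2 on DEX replicate 1 to 77.3 on Mock replicate 3. Pearson correlations across genes were 0.978 to 0.983 within groups and 0.975 to 0.981 between groups; genes are not independent replicates. Transcripts encoded in the organelles were low on Mock replicate 1, where the median deviation from each gene's mean was -0.52 on the log2 scale for chloroplast genes and -0.48 for mitochondrial genes. On the other 5 arrays these medians lay between -0.02 and 0.22.

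The comparison of DEX with Mock asks which transcripts differ shortly after the SUP fusion protein is activated. The transcript of SUP itself, which restrains stamen number and marks the inner border of the stamen whorl, was at 8.79 ± 0.09 in Mock and 8.88 ± 0.07 in DEX (log2 intensity, SD, n = 3). It was brighter than 79.2% of genes over all 6 arrays. The difference of 0.09 (SE 0.11) was within the spread between arrays (exact permutation p = 0.2). Whether the SUP feature reads the native transcript, the transgene or both was not tested, and a transcript level does not report where the protein was.

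Among 32627 genes, 16 fell and 1 rose after DEX (limma, adjusted p under 0.05). AT4G19380 fell by 3.71 (SE 0.14, adjusted p = 0.0132), from a mean intensity of 163 to 12.5. GRF7, a growth-regulating transcription factor, fell by 3.54 (SE 0.18, adjusted p = 0.0148), from a mean intensity of 442 to 38.1. EXPA5, an expansin that loosens cell walls, fell by 3.45 (SE 0.16) from 209 to 19.2. PIN4, an auxin efflux carrier, fell by 3.2 (SE 0.24) from 200.4 to 21.8. GASA6, a small gibberellin-regulated peptide, fell by 2.95 (SE 0.18), and OFP12, an ovate family protein, fell by 2.57 (SE 0.15). The serine carboxypeptidase-like gene scpl10 fell by 3.5 (SE 0.24), from a mean intensity of 40.6 to 3.58. AT1G60060, AT5G03700, AT3G26590, AT1G70720 and the amino acid export gene GDU2 also fell, with differences between -3.13 and -2.23. For scpl10, AT5G03700 and AT1G70720 the DEX intensities of 3.58, 3.52 and 5.88 were dim, and with 16 added to each intensity their differences were -1.53, -1.06 and -0.99. That setting shrank other falls too, to -2.65 for AT4G19380, -3.08 for GRF7, -2.67 for EXPA5, -2.51 for PIN4 and -1.59 for GDU2, so the order of the falls depends on it. The single rise was that of CSLB03, a cellulose synthase-like gene, by 1.87 (SE 0.10, adjusted p = 0.0208).

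Regulators of flower and shoot development were among the genes that fell. WUS, which maintains stem cells in shoot and floral meristems, fell by 1.29 (SE 0.10, adjusted p = 0.0470), from 7.17 ± 0.07 to 5.87 ± 0.06 (SD, n = 3). SPL, also known as NOZZLE and needed for sporogenous cells in anthers and ovules, fell by 1.28 (SE 0.10, adjusted p = 0.0470). TRY, a small MYB protein that limits trichome formation, fell by 2.2 (SE 0.14), and KDR, a small helix-loop-helix protein, fell by 1.59 (SE 0.13). TRY and KDR lie outside the naming rule and were chosen after their values were seen. The groups did not overlap for any of the 17 genes. Chance gives this for 10% of genes in a design of this size, but these 17 were picked by a small p. Their lack of overlap is thus no separate evidence. The floral organ identity genes did not pass. The differences were -0.18 (SE 0.11) for AP3, -0.32 (SE 0.16) for PI and -0.10 (SE 0.15) for AG. The boundary genes CUC1 and CUC2 differed by -0.37 (SE 0.13) and -0.06 (SE 0.16), with adjusted p = 0.404 and 0.923.

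YUC1 and YUC4, flavin monooxygenases of auxin synthesis in the flower, are known from work on SUP. YUC1 was at 6.80 ± 0.22 in Mock and 5.39 ± 0.14 in DEX (SD, n = 3), a difference of -1.41 (SE 0.16). All 3 DEX arrays lay below all 3 Mock arrays, but the gene did not pass over all genes (limma adjusted p = 0.0903; exact permutation p = 0.1, the smallest this design allows). It passed with a variance prior that follows intensity (adjusted p = 0.00289). YUC4 was at 6.29 ± 0.57 in Mock and 5.13 ± 0.25 in DEX, a difference of -1.16 (SE 0.31, adjusted p = 0.325; exact permutation p = 0.1). A second YUC4 feature, dim at a mean intensity of 1.5, differed by 1.21 (SE 0.48) in the opposite direction.

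**Figure D1:**
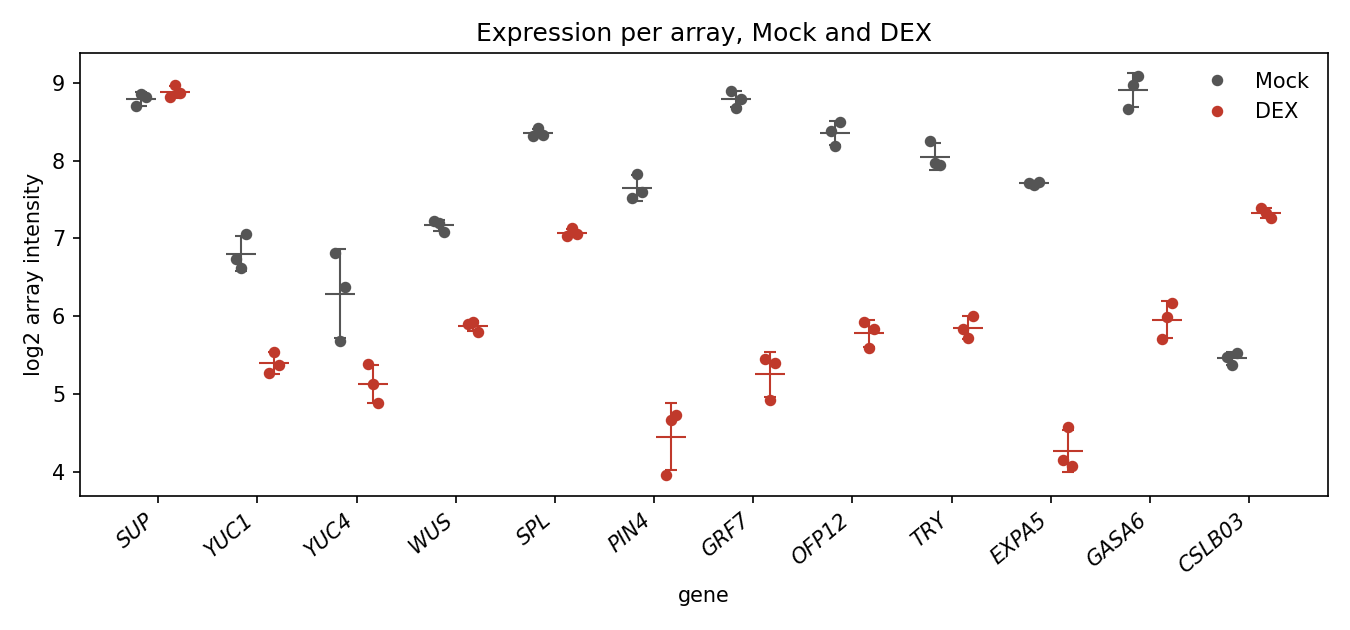
Log2 array intensity (y axis) of 12 genes (x axis) on each array, with Mock in grey and DEX in red; points are arrays, horizontal marks the mean and bars the SD (n = 3). SUP overlaps between groups, WUS lies at 7.17 in Mock and 5.87 in DEX, and CSLB03 alone of these is among the genes that rose.

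How many genes were called depended on the threshold, the prior and other settings. Under the default prior and the same threshold, the count was 282 without genes below the median intensity. Of the 17 genes, 9 were among these, and the others were dimmer than the median and so not tested there. The count was 204 when 16 was added to each intensity and 0 when the replicate block was a fixed factor. With the trended and robust prior, 347 genes fell and 84 rose, and all 17 genes were among them. Leaving out any 1 of the 6 arrays, Mock or DEX, left 0 calls with limma's default prior. At an unadjusted p under 0.05 those fits had 2806 to 3372 genes, where about 1631 are expected by chance. With the trended and robust prior and without Mock replicate 1, 203 fell and 41 rose.

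The 11 further genes taken by the naming rule for rises did not pass (adjusted p from 0.0898 to 0.0930). Their differences lay between 0.86 and 2.36. All 11 were dimmer than the median gene, whose intensity was 72.9, and 5 are listed as pseudogenes. AT5G43690 had the largest difference, 2.36 (SE 0.26), at mean intensities of 0.824 in Mock and 4.23 in DEX; with 16 added it was 0.27. The others were AT2G11530, AT4G03470, AT1G41720, AT2G27700, AT3G43930, AT5G28487, AT1G68430, AT1G37063, AT3G44117 and the tRNA locus AT3G09585. With 16 added, the differences of all 11 lay between 0.16 and 0.85. In that setting AT1G41720 (limma adjusted p = 0.0155), AT4G03470 (0.0213), AT1G68430 (0.0221), AT3G43930 (0.0266), AT1G37063 (0.0362) and AT2G27700 (0.0476) passed, and the rest did not.

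Auxin genes were lower in DEX as groups with camera's preset correlation. With an estimated correlation camera has only 4 residual degrees of freedom. The estimate was -0.018 for auxin synthesis and -0.016 for auxin transport, below the preset 0.01, so their larger p did not come from a higher correlation. For early auxin-induced genes it was 0.060. The 14 auxin synthesis genes had a median difference of -0.51, with 12 below 0 (camera adjusted p = 0.00397; adjusted p = 0.138 with an estimated correlation). None passed over all genes, and 4 were lower when adjusted over the list alone. Besides YUC1 and YUC4, the values were -0.82 (SE 0.21) for TAR2 and -0.65 (SE 0.16) for YUC6. Of 18 auxin transport genes, 15 were below 0 and the median was -0.27 (camera adjusted p = 0.00142; adjusted p = 0.138 with an estimated correlation). PIN4 fell, and 2 genes were lower when adjusted over the list alone. PIN3 was at -1.30 (SE 0.15) and LAX2, an influx carrier, at -0.45 (SE 0.12). Of 31 early auxin-induced genes, 22 were below 0, with a median of -0.42 (camera adjusted p = 0.0124; adjusted p = 0.287 with an estimated correlation; fry adjusted p = 0.123). The call ended without Mock replicate 2, DEX replicate 1 or DEX replicate 2 (camera adjusted p = 0.0873, 0.0528 and 0.0551). None passed over all genes, and 1 was higher when adjusted over the list alone. GH3.5 was at -1.01 (SE 0.23), GH3.2 at -0.75 (SE 0.21) and IAA17, an auxin-response repressor, at 1.41 (SE 0.21).

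Meristem and boundary regulators had the smallest p of the lists (camera adjusted p = 0.000537; adjusted p = 0.138 with an estimated correlation). Of 21 genes, 17 were below 0 and the median was -0.26. WUS fell; adjusted over the list alone, 5 were lower and 1 higher. BOP1 and BOP2, which shape organ bases, were at -1.65 (SE 0.20) and -0.80 (SE 0.10), and the boundary gene CUC3 was at 1.05 (SE 0.17). The 13 gibberellin genes had a median of -0.52 (camera adjusted p = 0.00477; adjusted p = 0.138 with an estimated correlation). GASA6 fell, and 4 were lower when adjusted over the list alone. GA2OX2, which inactivates gibberellin, was at -0.67 (SE 0.17), and GA20OX1, which makes it, at -0.79 (SE 0.20).

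The 4 other lists that passed were also lower. For jasmonate genes the estimated correlation was 0.386, far above the preset 0.01. The 20 jasmonate genes had a median of -0.21 (camera adjusted p = 0.0173; adjusted p = 0.718 with an estimated correlation; fry adjusted p = 0.328), with MYC2 at -0.91 (SE 0.12) and JAZ3 at 0.59 (SE 0.17). The 11 vascular markers had a median of -0.14 (camera adjusted p = 0.0232; adjusted p = 0.179 with an estimated correlation), with the cambium regulator WOX4 at -1.60 (SE 0.20; -1.0 with 16 added) and the phloem sucrose carrier SUC2 at -0.77 (SE 0.18). The 10 ovule and carpel markers had a median of -0.19 (camera adjusted p = 0.0285; adjusted p = 0.179 with an estimated correlation), with INO, an outer integument gene, at -2.01 (SE 0.30). INO was dim, at mean intensities of 20.3 and 5.03, and was at -0.80 with 16 added. The 24 cell wall loosening genes had a median of -0.15 (camera adjusted p = 0.0295; adjusted p = 0.179 with an estimated correlation); EXPA5 fell, and XTH15 was at -1.68 (SE 0.22). Adjusted over the list alone, 1, 2, 1 and 3 genes of these lists were lower. Without Mock replicate 2, these 4 lists and the early auxin-induced genes no longer passed (camera adjusted p = 0.193 for jasmonate, 0.197 for vascular, 0.103 for ovule and carpel and 0.133 for cell wall genes). Calls also ended without DEX replicate 1 for vascular (0.0643) and ovule and carpel (0.162), without DEX replicate 3 for jasmonate (0.258), ovule and carpel (0.0525) and cell wall genes (0.0634), and without Mock replicate 1 for cell wall genes (0.0695). The fixed replicate block ended those of vascular (camera adjusted p = 0.0742), ovule and carpel (0.0781) and cell wall genes (0.0781).

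The other 14 lists did not pass with camera. SPL was the only member of these lists called over all genes; the 22 floral identity genes had a median of -0.13 (camera adjusted p = 0.141; fry, which tests the list alone, adjusted p = 0.0154), with LFY at -0.82 (SE 0.18) and AP2 at 0.48 (SE 0.11). The organ growth list had a median of 0.06 (camera adjusted p = 0.571), with GRF5 at -0.78 (SE 0.10), CYP78A9 at 2.0 (SE 0.27; 0.62 with 16 added) and ROT3 at 0.92 (SE 0.17). The 10 reference genes had a median of 0.06 (camera adjusted p = 0.141; fry adjusted p = 0.0234, pointing up). Adjusted p was 0.525 for mitotic genes and for handling stress, 0.684 for cytokinin, anther and tapetum, and Polycomb and Trithorax genes, 0.808 for brassinosteroid genes and 0.879 for clock genes. It was 0.884 for the D-type cyclin and replication list, photosynthesis, epidermis and the SUP-like zinc fingers. For the SUP-like list the median was -0.02 while camera pointed up, and for the epidermis list the median was 0.09 while camera pointed down. Adjusted over the list alone, these lists had 5 genes higher and 6 lower, counted per list. ROT3 counts in both the organ growth and the brassinosteroid list.

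**Figure D2:**
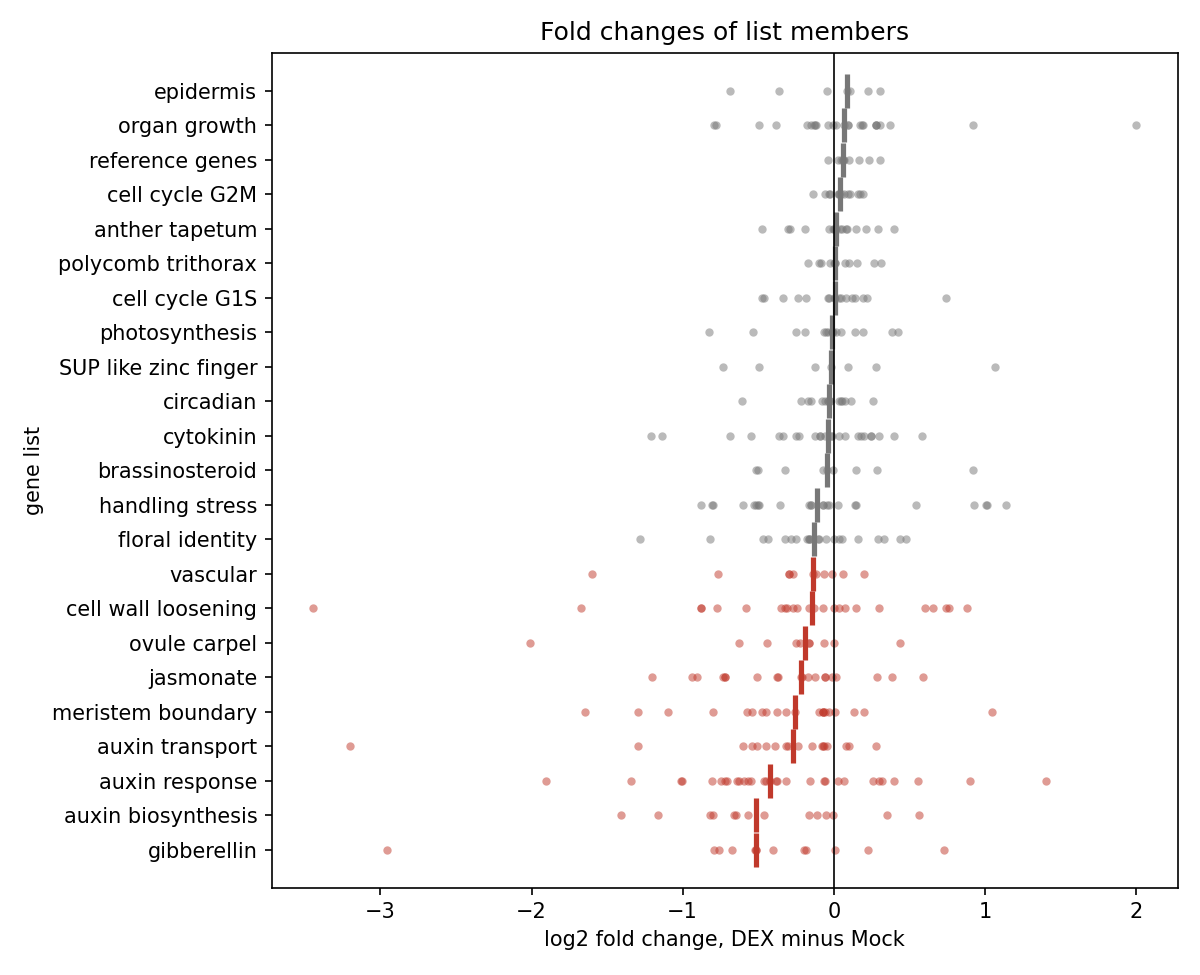
Log2 fold change, DEX minus Mock (x axis), of each member of the 23 gene lists (y axis, ordered by median); points are genes, vertical bars are list medians, and red marks the 9 lists with a camera adjusted p under 0.05. The 9 red lists have medians below 0, from -0.52 for gibberellin to -0.14 for vascular markers.

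No DEX-treated plants without the transgene were analysed here, so effects of DEX itself are included in every difference.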

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

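The tests of array scaling, of dim loci, of residual DNA and of splits for the gene count were chosen after their results were seen. The matched lists and the splits for the list count were set down beforehand.

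Features that did not stand for their gene in the comparison held 4 signals past an adjusted p of 0.05 when every feature was tested. Feature 1 of PIN4 differed by -3.52. Features 1 and 2 of BGLU11, a beta-glucosidase, each differed by -1.82, and feature 2 of KNATM, a KNOX-like gene without a homeodomain, by -2.06. The features that stood for BGLU11 and KNATM differed by -1.68 and -1.49, with adjusted p of 0.104 and 0.0898.

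Falls outnumbered rises by 16 to 1 among called genes. At an unadjusted p under 0.05 the counts were more even, 1933 lower and 1468 higher, where about 1631 in all are expected by chance. Among protein-coding genes, the class of all 17 called genes, 1727 were lower and 936 higher at that cut. Among loci listed as pseudogenes, 164 were lower and 440 higher. Of 4 ways of scaling the arrays, the one that centred on the reference genes moved DEX against Mock most, by 0.177, well below the smallest fall among the called genes, which was 1.28 (SE 0.10). That shift, of each array's median over the reference genes, would turn the sign of small differences such as the 0.09 of SUP. The median of the reference genes' own differences, 0.06, would not. With 10 splits of 6 arrays a share under 0.05 cannot be reached: 1 split, the real one, gave 17 genes, and the highest of the others gave 0. Neither an action of the SUP fusion nor one of DEX itself, shared by all treated plants, was tested.

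The 9 lists that passed were all lower in DEX. Protein-coding genes of matched intensity did not reach as low a mean t (difference over SE) in 5% of 10000 draws for any of the 9 lists. The highest share was 2.53%, for ovule and carpel markers. The draws used the same t values by which camera had picked these lists, so they give no separate support for them. They show only that matching moved little: mean t was -0.26 to -0.12 in the draws, and -2.43 to -0.93 in the lists. The draws ignore correlation between members. The estimated correlation was below 0 for 7 of the 9 lists. It was 0.060 for early auxin-induced and 0.386 for jasmonate genes, above the preset 0.01. These estimates rest on 4 residual degrees of freedom, so joint movement of linked genes stays open for all 9 lists. The splits number 10, too few for a share under 0.05: 1 split gave as many as 9 lists, and the highest of the others gave 2.

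Loci listed as pseudogenes, 4775 in all, were higher in DEX, with a median difference of 0.12 and all 3 DEX array medians above all 3 Mock medians (exact permutation p = 0.1, the smallest possible). The shift was 0.14 in the 3858 not listed as transcribed and 0.05 in the 917 listed as transcribed, where the arrays overlapped. An offset of all dim loci is argued against, since they exceeded protein-coding genes of the same intensity by 0.181, and by 0.157 to 0.193 with each array left out. Residual genomic DNA stays undecided. Of 8 other classes, 5 were higher on all 3 DEX arrays (tRNA, snoRNA, chloroplast, mitochondrial and other non-coding RNA loci). The mitochondrial ones were so narrowly, at 0.101 on Mock replicate 3 against 0.109 on DEX replicate 2. The gap was narrower still for the other non-coding RNA loci, at -0.0128 on Mock replicate 3 against -0.0108 on DEX replicate 1. Of these loci, 8 were higher and 8 lower at an unadjusted p under 0.05 (limma). Counts higher and lower at that cut were 14 and 4 for tRNA and 9 and 0 for snoRNA loci. They were 8 and 0 for chloroplast and 5 and 0 for mitochondrial loci. The arrays overlapped for lncRNA, miRNA and unmatched loci, the labels state DNase digestion, and the chloroplast median drops from 0.30 to 0.12 without Mock replicate 1. Release of silent loci by the treatment was not tested.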

How the results depend on the processing

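The count of genes changed moved most. Against 17, it was 105 without the dimmest 25% of genes, and 282 without genes below the median, with 9 of the 17 among them. It was 431 with the trended and robust prior, 96 at adjusted p under 0.1 and 2118 at unadjusted p with a 1.5-fold minimum. Alternatives chosen after seeing the data gave 204 with 16 added to each intensity, 750 with the replicate block and the trended and robust prior, and 244 with that prior and Mock replicate 1 left out. Leaving out each array gave 0 genes every time with limma. At an unadjusted p under 0.05 those fits, on fewer arrays, gave 2806 to 3372, where about 1631 are expected by chance. Apart from the fixed replicate block, the other alternatives gave 13 to 22.

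Same-numbered Mock and DEX arrays had deviations correlated at 0.03, 0.06 and 0.06 over all genes (mean 0.049), so the numbers were not taken to pair the arrays. Over genes above the median mean they were 0.11, 0.29 and 0.23 (mean 0.212), so pairing stays open. Each array of a group correlated best with the array of the same number in the other group. The stated design names sets of Mock and DEX samples but no paired test, nor whether equal numbers mark one set. With the replicate block as a fixed factor limma called 0 genes, against 3513 at an unadjusted p under 0.05; as a random block it called 20, all 17 among them. The fixed block left 6 lists, ending the calls of vascular (0.0742), ovule and carpel (0.0781) and cell wall genes (0.0781); in simulated arrays with no pairing the blocked fit recovered 0 of 100 genes changed by 2.

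SUP did not pass under any of its 19 alternatives, at 0.04 to 0.13. YUC1 kept its direction. It passed at -1.41 without the dimmest 25%, with the trended and robust prior and with the block and that prior, at -1.14 with 16 added, and at -1.44 with that prior and Mock replicate 1 left out; adjusted p ranged from 0.00193 to 0.299. YUC4 passed at -1.16 with the block and the trended and robust prior, and turned to 0.022 with the mean of all features, where the dim feature enters; adjusted p ranged from 0.0234 to 0.989. SEP3 turned to 0.085 in the same way. With each array left out, YUC1 lay between -1.50 and -1.28, YUC4 between -1.47 and -0.90, and CUC2 between -0.173 and 0.0577. For the 120 named genes, 1962 of 2227 values under alternatives kept direction and side of the threshold, 136 newly passed, 125 no longer passed and 4 changed sign.

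With an estimated correlation 0 lists passed, a test with only 4 residual degrees of freedom. With fry 9 passed, of which 7 also passed with camera; leaving out each array gave 4 to 9, with 4 without Mock replicate 2. Lists that never passed changed direction in places, at adjusted p of 0.959 for the D-type cyclin list with the replicate block, and 0.960 with median centring and 0.930 without the dimmest 25% for photosynthesis. With each array left out, adjusted p ranged from 0.708 to 0.991 for SUP-like zinc fingers, 0.150 to 0.979 for mitotic genes, 0.926 to 0.988 for the D-type cyclin list, 0.307 to 0.991 for brassinosteroid, 0.296 to 0.978 for handling stress, 0.645 to 0.991 for clock genes, 0.819 to 0.988 for photosynthesis and 0.855 to 0.979 for epidermis. Except where stated, the cause was not tested. Dim genes limit the precision: the median SE was 0.37 for genes below the median intensity and 0.13 above it.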

Other observations

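The test of gene families was set down before its result was seen, and the check of its power was chosen after. Genes were grouped by the stem of their symbol into 473 families of at least 5 members. The stems were not checked against known gene families. Stems that differ only in case, such as emb and EMB, were kept apart. With the preset correlation 2 families passed over all families. The 5 CSLB genes, cellulose synthase-like, were higher, with a median of 0.69 and 0 of 5 below 0 (camera adjusted p = 0.0393). They include CSLB03, the single called rise. The 5 IGMT genes, methyltransferases of indole glucosinolate synthesis, were lower, with a median of -0.99 and all 5 below 0 (camera adjusted p = 0.0393). The estimated correlation was 0.413 for CSLB and 0.178 for IGMT, well above the preset value under which they passed. With the estimated correlation both had adjusted p = 0.998, so the number of families past both tests was 0. That 0 decides nothing. Simulated DEX and Mock arrays of 32627 independent genes had 1 of 20 families at a time lowered by 1 on the log2 scale. There the estimated-correlation test found 2 and the preset one 20. As the simulated genes were independent, the 20 do not show how the preset test treats families of correlated genes. Whether families shift together stays open. The PIN auxin carriers were next, with 7 of 8 below 0 (camera adjusted p = 0.0549).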
